A study of Homo sapiens with 18 samples.

How the data were processed

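The samples were 18 arrays of total RNA labelled with biotin, from LNCaP (12 arrays) and VCaP (6 arrays), in 12 groups of cell line, siRNA and treatment. Per the labels' protocols, cells were transfected 48 h before hormone and kept for 3 days in serum treated with charcoal, at 2.5% for LNCaP and 5% for VCaP, before vehicle or R1881 was added. The duration of the hormone treatment is not given in the sources used here, and neither is the meaning of the mark on the siCTBP1-AS siRNA of set 2 and VCaP. The labels do not state that the arrays came from separate cultures, so p-values then measure only the spread between these samples, which may be technical.

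The deposited values are log2 signals per transcript cluster that the authors made with Affymetrix Expression Console 1.1.1 and RMA, per the submitters' processing notes. How the arrays were grouped for that normalization is not given in the sources used here. Within a set the value distributions matched closely, with a largest gap between array quantiles of 0.06, 0.08 and 0.09 log2 units in LNCaP sets 1, 2 and 3 and 0.11 in VCaP. The set medians were 6.7, 5.74, 6.8 and 6.25, so levels were compared within a set only. The exceptions are fits without a block, whose spread takes in the level differences between sets. Sets were taken from the array names in the labels, which number the arrays of each set together. Arrays in a set correlated at 0.978 to 0.989 in set 1, 0.974 to 0.993 in set 2, 0.982 to 0.992 in set 3 and 0.974 to 0.993 in VCaP, and no pair was identical.

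Of 33297 transcript clusters, 19460 had 1 gene symbol in the platform annotation, 1754 had several and 12083 were not listed there and stayed unnamed. Each of 18417 symbols was represented by its cluster with the highest mean over the 18 arrays, a choice that mattered for 769 genes with more than 1 cluster, and 0 symbols were updated through gene identifiers. The 25% of genes with the lowest mean over the arrays of a fit were left out, which left 13812 genes in each fit. Probes can read near-identical relatives, so values of UGT2B, AKR1C and taste receptor genes are uncertain. Gene lengths were taken from the RefSeq annotation of GRCh38 for 99.88% of the tested genes, as lengths only, since the array coordinates were not used here.

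Tests were made with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, using lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05. The androgen response in LNCaP used the 6 siControl arrays without a block. Effects in LNCaP used its 12 arrays, and effects over both lines all 18, with the set as a block, a term for R1881 (per cell line in the fit of 18 arrays), terms for each siRNA and their products with R1881. A knockdown effect is knockdown minus siControl averaged over vehicle and R1881, and a changed androgen response is the product term. The spread in these fits pools set differences in the knockdown effect with those in the R1881 response and the product terms. The p-values of a knockdown effect therefore measure only in part how it varies between sets. In the fit of 18 arrays siPSF is held by set 3 and VCaP, so the lines serve as its replicates, but its values are not the means of these sets. The siCTBP1-AS effect is shared by sets 1, 2 and VCaP and the R1881 response by the LNCaP sets, so arrays of other sets enter as well. Fits on only the sets that hold a knockdown are free of this but leave 2 to 5 residual degrees of freedom, and they are given beside many of the results they move, not all. VCaP alone has 1 array per group, and its androgen response was not tested on its own. There, a list's median was placed among 10000 random lists of the same size matched on mean expression. The replicate numbers pair the siControl arrays of LNCaP, because same-numbered arrays share a set, and their deviations from the group means correlated at 0.78, 0.84 and 0.7, against -0.64 to -0.08 for arrays of different number. Shares carry exact Clopper-Pearson intervals at 95% confidence. Correlations across genes are descriptive, since genes are not independent replicates.

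Gene lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over the lists of a comparison, for lists with at least 5 measured members. The lists were androgen-induced, androgen-repressed, DNA replication, mitosis, cell cycle inhibitors, TGF-beta pathway, corepressor complex, paraspeckle, splicing factors, cholesterol synthesis, fatty acid synthesis, unfolded protein response, interferon response, immediate early, hypoxia, polyamine, neuroendocrine, luminal prostate, EMT, ribosomal proteins, RNA interference machinery and cell line markers, with markers of basal epithelium, fibroblasts, leukocytes and endothelium. The endothelium list had fewer than 5 measured members and was not tested. Of the 27 lists fixed, 1 is not reported here, nor are 4 of the genes meant to be named in every comparison. The R1881-responsive genes used for the changed response were those with a log2 difference of at least 1, or at most -1, in both siControl pairs of the sets not tested.

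The genes named for each comparison were the 10 highest and 10 lowest log2 changes among genes that passed and moved the same way in every difference within a set or replicate. Where fewer than 3 passed, the 5 genes with the smallest p were given as values that did not pass. SFPQ, CTBP1, KLK3, SMAD3 and genes named for CTBP1-AS were also given, with up to 4 members with the largest change from each list described. Genes named from the blocked androgen fit, KLF6 and ZFP36 under siCTBP1-AS, the largest line differences, FAS, LYZ and MX1 were chosen after their values were seen. The groups, the tests of the comparisons, the lists, the rule for named genes and the alternatives were chosen before the data were examined. The exceptions are the length comparison, which was made after the siPSF calls were seen, and the tests of lists on only the sets that hold a knockdown and of VCaP alone without product terms, which were added after seeing the data.

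Alternatives were no filter, leaving out the lowest 50% of genes, quantile normalization again, median centring, eBayes with trend and robust, array weights, the block added or left out, the set as a random block, fits on fewer or more arrays, each set or replicate left out, every transcript cluster tested, other thresholds for the held-out genes, and the other list tests. Background correction was part of RMA and was not changed.

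The steps were tested on simulated data made from the spread of the real arrays, with 200 of 13812 genes changed in 20 runs. The share recovered at log2 changes of 0.5, 1 and 2 was 19.5%, 86% and 99.3% for siCTBP1-AS in LNCaP, 64.9%, 95.7% and 99.8% for siCTBP1-AS over both lines, 47.4%, 93.5% and 99.4% for siPSF, 32%, 88.1% and 99.2% for siCTBP1-AS against siPSF and 3.2%, 50.7% and 93.4% for the changed response with siPSF. For the androgen response it was 0% at each size without the block and 3.8%, 82.5% and 99.5% with it. False calls were between 0 and 5.62% of calls. On lists of 25 unchanged genes, camera called 2.92%, camera with an estimated correlation 0.52% and fry 6.04% at an unadjusted p under 0.05. The simulated genes varied independently of each other. In the real fit of siCTBP1-AS in LNCaP the estimated correlation was 0.53 for interferon and 0.75 for DNA replication genes. These shares therefore do not show how often the tests call unchanged lists whose genes vary together.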

Results

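Gene expression was measured on 18 gene-level arrays of total RNA from LNCaP and VCaP, lines of human prostate cancer cells that respond to androgen. Cells were transfected with a control siRNA (siControl), with siRNA against CTBP1-AS, an RNA transcribed antisense to the corepressor gene CTBP1, or with siRNA against PSF, the RNA-binding protein encoded by SFPQ. Each transfection was followed by vehicle or R1881, a synthetic androgen. The arrays fell into 4 sets, each with its own siControl arrays for vehicle and R1881. LNCaP set 1 held siControl and siCTBP1-AS at 10 nM R1881, set 2 held siControl and siCTBP1-AS at 1 nM, and set 3 held siControl and siPSF at 10 nM. The VCaP set held siControl, siCTBP1-AS and siPSF at 1 nM. Set 1, set 2 and set 3 held 4 arrays each and the VCaP set 6, with 1 array for each siRNA and treatment. Values were log2 RMA signals, and within a set the arrays correlated at 0.974 to 0.993 across genes, which are not independent replicates. The number of arrays limited the precision of every comparison.

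The first question for each knockdown was whether its target was lower. SFPQ fell by 1.18 on the log2 scale (SE 0.14, adjusted p = 0.000748) with siPSF in the fit of all 18 arrays. On only set 3 and VCaP, the sets that held siPSF, its change was -1.12 (SE 0.16, adjusted p = 0.0734), which passed over the paraspeckle list alone and not over all genes. In set 3 the SFPQ signal was 11.15 in vehicle and 10.79 in R1881 with siControl, against 10.47 and 9.89 with siPSF. In VCaP it was 11.02 and 11.16 with siControl, against 9.7 and 9.61 with siPSF. With siCTBP1-AS the SFPQ signal was 10.25 and 10.13 in set 1, next to 10.34 and 10.34 with siControl. In set 2 it was 10.43 and 10.21 with siCTBP1-AS, next to 10.49 and 10.24, and in VCaP 11.26 and 11.15. CTBP1-AS itself was not analysed here, so the siCTBP1-AS arrays were not checked on their own target. CTBP1, its partner on the opposite strand, had signals of 9.91 in vehicle and 9.51 in R1881 with siControl and of 9.67 and 9.37 with siCTBP1-AS in set 1. In set 2 these were 10.26 and 9.06 with siControl, and 9.62 and 9.25 with siCTBP1-AS. In set 3 they were 10.69 and 9.68 with siControl, and 10.72 and 10.34 with siPSF. In VCaP CTBP1 stood at 10.93 and 10.55 with siControl, at 10.97 and 10.84 with siCTBP1-AS, and at 10.96 and 10.66 with siPSF. Signals were compared within a set only, because the sets had been scaled separately as far as their value distributions show.

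**Figure D1:**
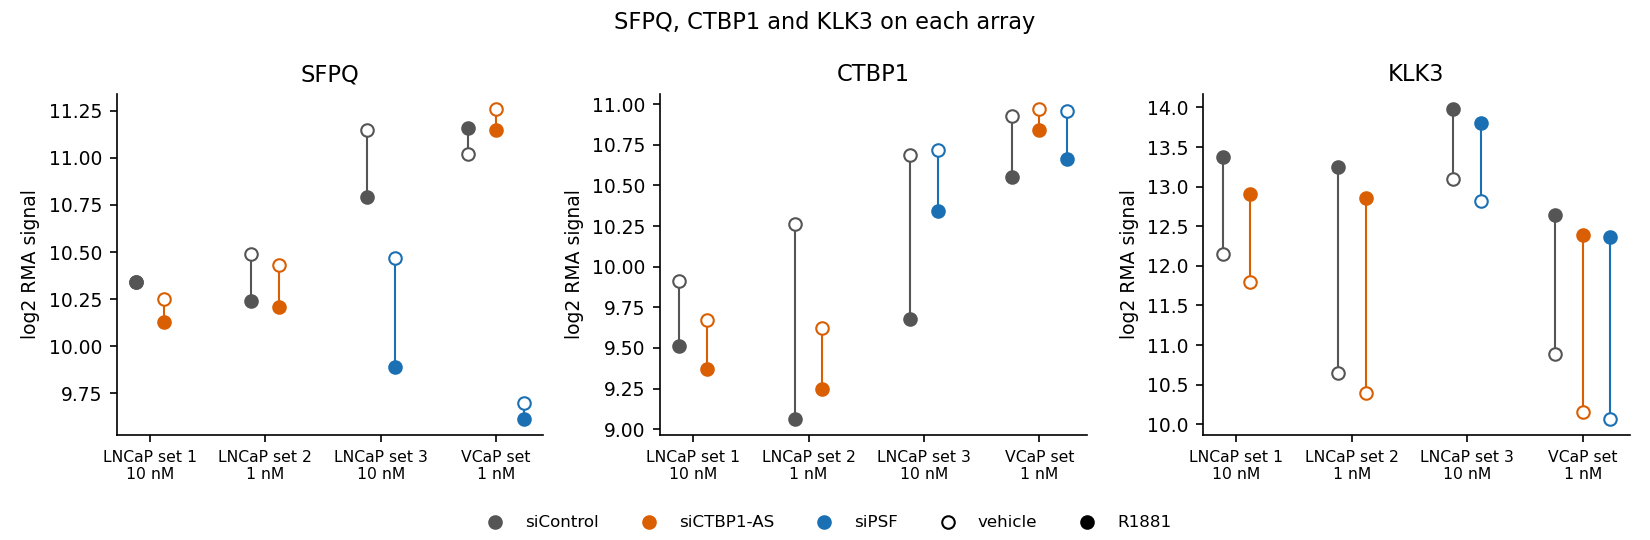
Log2 RMA signal of SFPQ, CTBP1 and KLK3 on each of the 18 arrays, by set, with open points for vehicle and filled points for R1881, and grey for siControl, orange for siCTBP1-AS and blue for siPSF. SFPQ lay lower with siPSF than with siControl in both sets that held siPSF, and KLK3 lay higher with R1881 than with vehicle in all 9 pairs of arrays.

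The response to R1881 in LNCaP with siControl (3 arrays against 3) served as the reference for androgen-dependent expression. This fit did not pair the arrays of a set, so level differences between sets entered its spread and its p-values. The paired fit, which called 734 genes, is given further below, and the values that follow first are from the unpaired fit. STEAP4, a metalloreductase gene, rose 118-fold (log2 6.88, SE 0.46, adjusted p = 5.01e-07). TARP rose by 4.74 (SE 0.59), SNAI2, a transcription factor of epithelial-mesenchymal transition, by 4.48 (SE 0.52), and HPGD, which degrades prostaglandins, by 4.13 (SE 0.56). SI, encoding sucrase-isomaltase, fell by 3.06 (SE 0.45) and OPRK1, encoding the kappa opioid receptor, fell by 2.49 (SE 0.45). In all, limma called 35 of 13812 genes, 31 higher and 4 lower, and each of the 35 moved the same way in all 3 replicates. The other large increases were CCDC141 at 3.89, CHRNA2 at 3.36, UGT2B28 at 3.26, INPP4B at 3.18, PGC at 3.15 and ST6GALNAC1 at 3.05, and the remaining decreases were MAN1A1 at -2.46 and LRRC31 at -2.28. UGT2B28 belongs to a family of near-identical genes, so its value is uncertain.

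Among genes known to be induced by androgen, 12 of 31 rose and none fell, and 29 rose when p-values were adjusted over the list alone. PMEPA1 and SLC45A3 rose by 3.04 each (SE 0.48 and 0.44), while KLK3, which encodes prostate-specific antigen, had a log2 change of 1.57 with an adjusted p of 0.988. KLK3 passed once the arrays were paired, as given further below. Of 11 genes known to be repressed by androgen, SI and OPRK1 fell, and 6 fell when adjusted over the list alone. The camera test called the induced list up (adjusted p = 2.26e-127) and the repressed list down (adjusted p = 5.38e-22), and adjusted p was 0.0657 for each with an estimated correlation. ELOVL7, a fatty acid elongase, rose by 2.81 (SE 0.49) as the 1 passing member of 15 in the fatty acid list, and SPDEF rose by 2.13 (SE 0.43) as the 1 of 12 in the luminal prostate list. Adjusted over the list alone, 2 and 3 members rose in these lists, and both were called up by camera (adjusted p = 1.38e-15 and 0.000463). With an estimated correlation their adjusted p was 0.454 and 0.574.

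Several lists were called by camera with its preset correlation although none of their members passed limma over all genes. The cholesterol list had a median of 0.74 over 18 genes, with 3 genes at an unadjusted p under 0.05 and 2 passing when adjusted over the list alone (camera adjusted p = 1.16e-14, and adjusted p = 0.54 with an estimated correlation). The interferon response list had a median of -0.62 over 24 genes, with 2 genes at an unadjusted p under 0.05 and 0 passing when adjusted over the list alone (camera adjusted p = 1.01e-09, and adjusted p = 0.574 with an estimated correlation). The hypoxia list had a median of 0.23 with 1 gene at an unadjusted p under 0.05 (camera adjusted p = 5.55e-05, and adjusted p = 0.805 with an estimated correlation). The polyamine list had a median of 0.11, with 3 genes at an unadjusted p under 0.05 and 2 passing over the list alone (camera adjusted p = 2.78e-05, and adjusted p = 0.574 with an estimated correlation). The immediate early list had a median of 0 and a mean of 0.23, with 1 member passing over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.982 with an estimated correlation). The DNA replication list had a median of -0.19 with 0 genes at an unadjusted p under 0.05 (camera adjusted p = 0.04, and adjusted p = 0.982 with an estimated correlation). Several of these values varied between sets. In sets 1, 2 and 3 the interferon list had medians of -1.31, -0.36 and -0.17, the hypoxia list of 0.52, 0.19 and 0.18 and the luminal list of 0.29, 0.03 and 0.51, while the DNA replication list, at 0.11, 0.31 and -1.05, was below 0 in set 3 alone. No camera call in any comparison held with an estimated correlation. That loss does not by itself show that correlation between genes made the calls. With replicate number as a block, the androgen-repressed list had an estimated correlation of -0.03, below the preset 0.01. Its camera adjusted p still went from 5.6e-09 to 0.269. The variant with an estimated correlation was thus stricter with so few arrays even where no correlation was found.

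The remaining lists reported here were not called by camera. PMEPA1 was the 1 of 20 TGF-beta pathway genes that rose, over all genes and over the list alone, and that list had a median of -0.04 and a mean of 0.18. SNAI2 was the 1 of 6 EMT genes that rose, again both ways, with a median of -0.17 and a mean of 0.58. Median changes were -0.13 for mitosis, -0.16 for cell cycle inhibitors, -0.04 for the corepressor complex, -0.13 for paraspeckle genes, -0.06 for splicing factors and 0.1 for the unfolded protein response. Ribosomal protein genes had a median of -0.08 and the RNA interference machinery of -0.13. Markers of other cell types had medians of 0.06 for basal epithelium, -0.03 for fibroblasts and 0.1 for leukocytes. In each of these lists limma called 0 genes, over all genes and over the list alone, and 0 members reached an unadjusted p under 0.05. The neuroendocrine list had a median of -0.02, and DDC, at -1.53, passed over the list alone.

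With replicate number as a block, which pairs the siControl arrays within their set, limma called 734 genes, 401 higher and 333 lower, among them all 35 above. The blocked fit added SLC38A4 at 3.17 (adjusted p = 0.0449), LRRN1 at -3.11, MMP16 at -2.64 and CBLN2 at -2.44. KLK3 rose (adjusted p = 0.0382), CTBP1 fell by 0.87 (SE 0.17, adjusted p = 0.035) and SMAD3, a mediator of TGF-beta signalling, fell by 0.73 (adjusted p = 0.0301). Of the lists, 28 androgen-induced genes rose, and 8 androgen-repressed genes fell while 1 rose. In sterol synthesis 11 genes rose, among them INSIG1 by 1.81 and HMGCS1 by 1.72, and in fatty acid synthesis 9, among them FASN by 1.7 and ACACA by 1.02. SMS at 1.87, ODC1 at 1.56 and SAT1 at 1.16 rose in the polyamine list, NR4A1 at 1.87, KLF4 at 1.41 and KLF6 at 0.59 in the immediate early list, and 3 genes in the hypoxia list, among them ANKRD37 at 1.53. In the luminal list 4 genes rose, among them KRT8 by 1.33, while ACP3, encoding prostatic acid phosphatase, fell by 1.49. In the interferon list 3 genes fell, among them RIGI, a sensor of viral RNA, by 1.26. In the TGF-beta list PMEPA1 and THBS1 rose and SMAD3 fell, in the neuroendocrine list DDC fell, and CTBP1 and SMAD3 were the 1 gene each that fell in the corepressor and cell cycle inhibitor lists. Adjusted over the list alone, the counts were 29 and 0 for induced, 1 and 9 for repressed, 16 and 1 for cholesterol, 13 and 0 for fatty acid, 3 and 0 for polyamine, 6 and 1 for immediate early, 6 and 0 for hypoxia, 6 and 3 for luminal and 0 and 5 for interferon genes, higher and lower in turn. They were 2 and 1 for TGF-beta, 0 and 1 for neuroendocrine, 1 and 1 for corepressor and 1 and 3 for cell cycle inhibitor genes. With the block camera no longer called the luminal, immediate early and DNA replication lists (adjusted p = 0.0944, 0.0989 and 0.185). The fry test, which asks whether the genes of a list move one way and does not compare them with other genes, called the induced, repressed, cholesterol, fatty acid, polyamine and luminal lists (adjusted p = 0.0149, 0.0126, 0.0169, 0.0121, 0.00478 and 0.0121), and the EMT and cell cycle inhibitor lists (adjusted p = 0.0121 and 0.0187). It called none of the 25 lists without the block. Leaving out 1 replicate in the fit without the block left 20 genes without replicate 1, 2 without replicate 2 and 0 without replicate 3. In the last fit 212 genes had an unadjusted p under 0.05, fewer than that threshold gives by chance.

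In VCaP siControl had 1 array per treatment, and its response is given as values without a test of its own. STEAP4 was again far higher with R1881 (log2 5.46, 44.1-fold), followed by ORM2 at 4.73, CST1 at 3.44, CST2 at 3.37 and LIPG at 3.24. The lowest values were WNT2 at -4.56, SYTL2 at -3.88, NAALAD2 at -3.71, CCN3 at -3.69 and HGF at -3.45. Of the 35 genes called in LNCaP, 34 had the same sign in VCaP (97.14%, exact Clopper-Pearson interval 85.08 to 99.93%). That interval counts genes as independent, which they are not, and does not measure the spread between VCaP arrays. The androgen-induced list had a median of 0.92, at percentile 100 among 10000 random lists of matched expression, and the repressed list a median of -2.07, at percentile 0. DNA replication genes had a median of -1.61 and mitosis genes of -0.72, both at percentile 0. Cholesterol and fatty acid genes had medians of 0.97 and 0.92, both at percentile 100. The cell line marker list, which included KLK3, SLC45A3 and ERG, had a median of 1.72 over 5 genes.

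The effect of siCTBP1-AS in LNCaP was asked over both treatments, in sets 1 and 2. Its p-values measure only in part how the effect varies between these sets, since the spread also pools set differences in the R1881 response. Interferon-stimulated genes rose most. CXCL10, a chemokine gene, rose by 4.37 (SE 0.68, adjusted p = 0.037), IFIT1 by 4.33 (SE 0.36, adjusted p = 0.00443), RSAD2 by 4.04 (SE 0.32), IFIT2 by 4.03 (SE 0.24, adjusted p = 0.00124), IFI44L by 3.92 and OAS1, which senses double-stranded RNA, by 3.73. SAMD9 at 3.57, XAF1 at 3.54, IFIT3 at 3.53 and CCL5 at 2.97 completed the highest group. Of 28 interferon response genes 20 rose and none fell, and 27 rose when adjusted over the list alone. Camera called the list up (adjusted p = 3.13e-38), with an adjusted p of 0.473 with an estimated correlation, and fry called it as well (adjusted p = 0.0286). On only sets 1 and 2, 16 of the 28 genes rose and 26 over the list alone, fry no longer called the list (adjusted p = 0.0931), and CXCL10, XAF1 and IFIT3 kept their values but did not pass (adjusted p = 0.0863, 0.089 and 0.0787). Its median was 2.91 in set 1 and 2.22 in set 2.

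Decreases with siCTBP1-AS in LNCaP were smaller. MAP1B, a microtubule-associated protein gene, fell by 1.35 (SE 0.21), MMP16 by 1.31 (SE 0.16), NMNAT2 by 1.16 (SE 0.12) and PRKCA, which encodes protein kinase C alpha, by 1.11 (SE 0.13). RBM24 fell by 1.06, PSAT1, an enzyme of serine synthesis, by 0.97, SEPTIN11 and STC2 by 0.95 each, and ARG2 and CDK16 by 0.94 each. Limma called 128 of 13812 genes, 85 higher and 43 lower, and 127 of them moved the same way in every difference within a set. THBS1, encoding thrombospondin-1, rose by 2.21 (SE 0.31, adjusted p = 0.024) as the 1 of 20 TGF-beta pathway genes, with 1 higher and 1 lower over the list alone, a median of -0.02 and a mean of 0.06. FAS, a death receptor gene, rose by 0.77 (SE 0.1, adjusted p = 0.0209). On only sets 1 and 2 adjusted p was 0.059 for THBS1, 0.0507 for FAS, 0.108 for RBM24, 0.0828 for PSAT1, 0.0793 for STC2 and 0.089 for CDK16. None of CTBP1 at -0.21 (adjusted p = 0.452), KLK3 at -0.37 (adjusted p = 0.568) and CTBP1-DT, a divergent transcript at the CTBP1 locus, at -0.56 (adjusted p = 0.145) passed.

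With siCTBP1-AS in LNCaP limma called 0 genes in the unfolded protein response, immediate early, DNA replication, androgen-induced and leukocyte lists. The unfolded protein response list had a median of -0.53 over 22 genes, with 6 at an unadjusted p under 0.05 and 0 over the list alone (camera adjusted p = 0.00173, and adjusted p = 0.836 with an estimated correlation). The immediate early list had a median of 0.23, with 7 genes at an unadjusted p under 0.05 and 1 higher over the list alone (camera adjusted p = 0.0055, and adjusted p = 0.836 with an estimated correlation). DNA replication genes had a median of -0.19, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0201, and adjusted p = 0.858 with an estimated correlation). Androgen-induced genes had a median of -0.26, with 6 at an unadjusted p under 0.05 and 3 lower over the list alone, among them ABCC4 at -1.19 and ODC1 at -0.89 (camera adjusted p = 0.0273, and adjusted p = 0.836 with an estimated correlation). Among markers of other cell types, the leukocyte list had a median of 0.11 over 5 genes, with 1 at an unadjusted p under 0.05, and CD68, at 0.98, passed over the list alone. The unfolded protein response value rested on set 1, with medians of -0.86 there and -0.1 in set 2, and the androgen-induced value on set 2, with 0.02 and -0.39. Medians in sets 1 and 2 were 0.29 and 0.13 for immediate early genes and -0.15 and -0.31 for DNA replication genes. Without set 2 the count was 145 and without set 1 it was 1684.

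**Figure D2:**
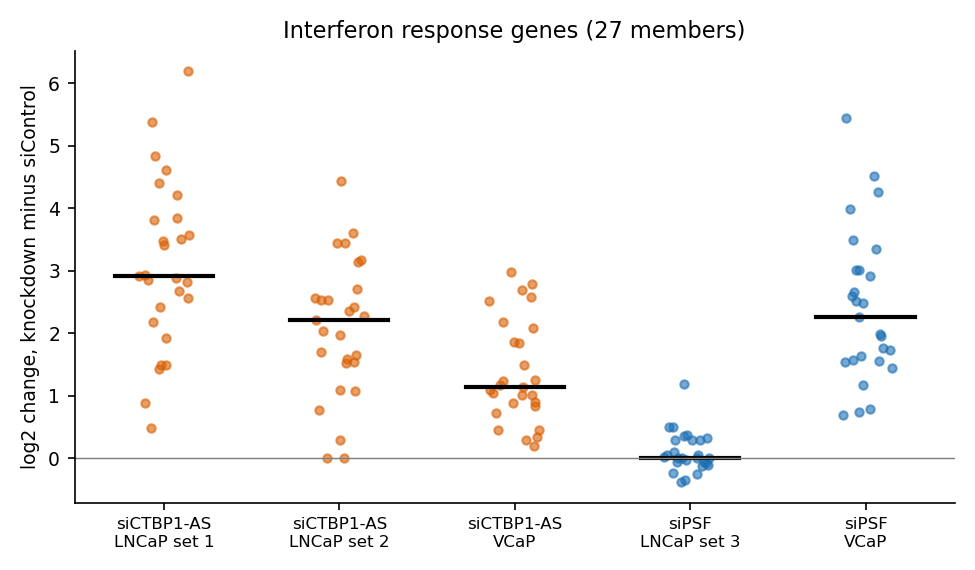
Log2 change, knockdown minus siControl and averaged over vehicle and R1881, of 27 interferon response genes (points) in each set, with the median as a black line. Medians were 2.91 and 2.22 with siCTBP1-AS in LNCaP sets 1 and 2, 1.14 with siCTBP1-AS in VCaP, 0.01 with siPSF in LNCaP set 3 and 2.26 with siPSF in VCaP.

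The average effect of siCTBP1-AS over both lines was tested with sets 1, 2 and VCaP, 2 of these 3 sets being LNCaP. RSAD2 rose by 3.12 (SE 0.57, adjusted p = 0.0444) and OAS1 by 2.84 (SE 0.48), with IFI44 at 2.42, RIGI at 1.87, IRF9 at 1.82 and IFI35 at 1.46. AKR1C1, an aldo-keto reductase gene with close relatives, rose by 2 (SE 0.27, adjusted p = 0.0164), CXCL8 by 1.57, HCP5 by 1.18 and HMOX1, encoding heme oxygenase 1, by 1.17 (SE 0.2). ARG2, a mitochondrial arginase gene, fell by 0.97 (SE 0.1, adjusted p = 0.00363), LRIG1 by 0.78, GOLM2 by 0.76 (SE 0.07, adjusted p = 0.00144), PLEKHH1 by 0.73, PCDHB14 and QSER1 by 0.71 each, UTRN and MPV17L by 0.7 each, and SASH1 and PYCR1 by 0.68 each. Limma called 78 genes, 31 higher and 47 lower, against 48 higher and 36 lower after quantile normalization was applied again. Of the 78, 75 moved the same way in every difference within a set, and 29 were also called in LNCaP alone. CTBP1 at -0.05, SFPQ at 0.04, KLK3 at -0.38 and CTBP1-DT at -0.53 (adjusted p = 0.0566) did not pass.

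Of 27 interferon response genes 5 rose with siCTBP1-AS over both lines and 26 rose over the list alone (camera adjusted p = 4.56e-26, and adjusted p = 0.395 with an estimated correlation). Of 17 immediate early genes, KLF6 at 0.49 and ZFP36 at 0.59 rose, and adjusted over the list alone 11 were higher, among them EGR1 at 0.85, and 1 lower (camera adjusted p = 4.94e-08, and adjusted p = 0.395 with an estimated correlation). In the luminal list limma called 0 of 12 genes with 5 at an unadjusted p under 0.05, and over the list alone 1 was higher and 4 lower, with a median of -0.16. Fry called the interferon, immediate early and luminal lists (adjusted p = 0.0453 each). Limma called 0 genes in the androgen-induced list (median -0.23, 10 genes at an unadjusted p under 0.05, 4 lower over the list alone), the fatty acid list (median -0.14, 4 genes at an unadjusted p under 0.05, 3 lower over the list alone) and the ribosomal list (median -0.09, 5 genes at an unadjusted p under 0.05). Camera called these lists down (adjusted p = 0.00962, 0.0374 and 0.0374), with adjusted p of 0.52, 0.558 and 0.724 with an estimated correlation. In sets 1, 2 and VCaP the medians were 0.02, -0.39 and -0.13 for androgen-induced genes, 0.04, -0.22 and -0.23 for fatty acid genes, -0.09, 0.02 and -0.19 for ribosomal genes and 0.29, 0.13 and 0.78 for immediate early genes. A fit on only these sets called 49 genes, and camera no longer called the fatty acid list (adjusted p = 0.166), nor fry the immediate early list (adjusted p = 0.172). There 14 of 28 interferon genes rose and 28 over the list alone, among them IFIT1 by 3.81 (adjusted p = 0.00705), 1 of 17 immediate early genes rose and 8 over the list alone, and in the androgen-induced list 1 gene was lower over the list alone. CXCL8, LRIG1, PCDHB14, MPV17L, SASH1 and PYCR1 did not pass (adjusted p = 0.0906, 0.0906, 0.109, 0.0519, 0.0871 and 0.081). The count of calls was 2 without set 1, 7 without set 2 and 128 without VCaP.

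The effect of siPSF was tested in the fit of all 18 arrays, in which set 3 and VCaP held siPSF with 1 pair of arrays per treatment. Decreases dominated, with 26 genes higher and 174 lower among 200 calls, of which 197 moved the same way in every difference within a set. A fit on only set 3 and VCaP called 54 genes, 4 higher and 50 lower, of which 41 were among the 200. There CLYBL, NAALADL2, NFIA, TAS2R14, PEMT, CSTPP1 and MBD5 still passed, while PRKCA, ZHX2 and PRLR did not (adjusted p = 0.0554, 0.0734 and 0.268), nor did IFI44L at 3.31 (adjusted p = 0.226), JUN at 0.93 (adjusted p = 0.0583), LIX1, CFAP69, ELF5, IQCN, DUSP10, SOWAHB and IL1RAP. PRKCA fell by 1.61 (SE 0.27, adjusted p = 0.0105), CLYBL by 1.57 (SE 0.21), NAALADL2 by 1.55 (SE 0.15, adjusted p = 0.000222), ZHX2 by 1.51, NFIA, a nuclear factor I transcription factor gene, by 1.36 (SE 0.13), TAS2R14 by 1.36 (SE 0.1, adjusted p = 7.58e-05) and PEMT, which makes phosphatidylcholine, by 1.36 (SE 0.12). PRLR, the prolactin receptor gene, fell by 1.3, CSTPP1 by 1.29 and MBD5 by 1.25 (SE 0.09). TAS2R14 overlaps relatives in a cluster of taste receptor genes. IFI44L rose by 3.76 (SE 0.82, adjusted p = 0.0459), with values of 1.19 in set 3 and 5.44 in VCaP. LIX1 rose by 1.71, CFAP69 and ELF5 by 0.97 each, JUN by 0.81 (SE 0.18), IQCN by 0.72, DUSP10 by 0.69, SOWAHB by 0.63 and IL1RAP by 0.61. Neither KLK3 at -0.39 (adjusted p = 0.575) nor CTBP1 at 0.13 passed.

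In the paraspeckle list, 11 genes including the partners of PSF, SFPQ fell and PSPC1, its paralog, rose by 0.68 (SE 0.1, adjusted p = 0.00565), both also over the list alone. On only set 3 and VCaP both passed over the list alone and neither over all genes (adjusted p = 0.104 for PSPC1). The median of that list was 0.08 and the mean -0.01. Of 27 interferon genes IFI44L rose and 21 rose over the list alone (median 1.44, camera adjusted p = 1.19e-17, and adjusted p = 0.869 with an estimated correlation). Within sets the median of that list was 0.01 in set 3 and 2.26 in VCaP. On only these sets limma called 0 interferon genes, with 10 at an unadjusted p under 0.05 and 1 higher over the list alone (median 1.14, camera adjusted p = 7.6e-12, and adjusted p = 0.762 with an estimated correlation). JUN was the 1 of 17 immediate early genes that rose (2 over the list alone, median 0.16). PGK1, a glycolytic enzyme gene, was the 1 of 19 hypoxia genes that fell, by 0.53 (SE 0.1), also over the list alone. On only set 3 and VCaP limma called 0 immediate early genes, with 10 at an unadjusted p under 0.05, and over the list alone 3 were higher and 1 lower (median 0.22, camera adjusted p = 0.00194, and adjusted p = 0.762 with an estimated correlation). There PGK1 did not pass (adjusted p = 0.149), while CHAC1, a gene of the unfolded protein response, rose by 1.38 (adjusted p = 0.035). Limma called 0 of 22 ribosomal protein genes, with 4 at an unadjusted p under 0.05 and 4 lower over the list alone (median -0.14, camera adjusted p = 0.000238, and adjusted p = 0.869 with an estimated correlation), and the medians were -0.02 in set 3 and -0.27 in VCaP. It called 0 of 23 splicing factor genes with 2 at an unadjusted p under 0.05, and SRSF4, at -0.4, passed over the list alone. It called 0 of 22 TGF-beta pathway genes with 7 at an unadjusted p under 0.05 and 3 higher over the list alone, a median of 0.11. It called 0 of 31 androgen-induced genes with 4 at an unadjusted p under 0.05, a median of -0.17. The count of calls was 146 without set 3 and 1 without VCaP.

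The 174 genes lower with siPSF were long. Their median gene length was 218 kb, and 89 of them (51.1%) spanned over 200 kb, against a median of 25.4 kb among genes not called and 42.3 kb among the 26 higher genes. In set 3, 20.95% of genes over 200 kb had a log2 change of -0.5 or lower with siPSF, against 1.7% of genes under 20 kb. In VCaP these were 20.95% and 2.32%. The R1881 response with siControl also had long genes at -0.5 or lower, 10.41% of genes over 200 kb against 3.33% under 20 kb in set 1, 22.72% against 5.69% in set 2, 13.96% against 4.94% in set 3 and 20.59% against 10.9% in VCaP. Among the 43 genes lower with siCTBP1-AS in LNCaP the median was 70.1 kb and 10 (23.3%) spanned over 200 kb.

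**Figure D3:**
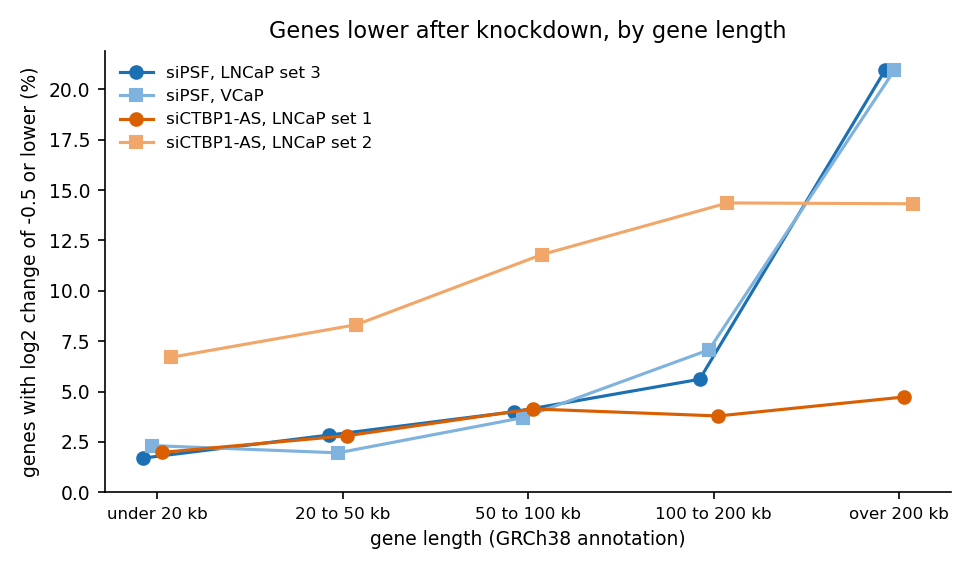
Percent of genes with a log2 change of -0.5 or lower (knockdown minus siControl) in 5 classes of gene length, for siPSF in LNCaP set 3 and VCaP and siCTBP1-AS in LNCaP sets 1 and 2. With siPSF the share reached 20.95% above 200 kb in both sets, against 4.73% and 14.32% with siCTBP1-AS in sets 1 and 2. With siCTBP1-AS in VCaP, not drawn here, it was 5.21%, against the same siControl arrays as siPSF. The R1881 response with siControl, also not drawn, had 10.41%, 22.72% and 13.96% in sets 1, 2 and 3 and 20.59% in VCaP.

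The knockdowns were set against each other within the 18-array fit, as the siCTBP1-AS effect minus the siPSF effect. Limma called 91 genes, 71 higher and 20 lower. All 91 had the same direction in vehicle and in R1881 in VCaP, where alone this could be checked. SFPQ was higher by 1.22 (SE 0.15, adjusted p = 0.00393), as were SORBS2 by 1.47 (SE 0.25), RTN1 by 1.46 (SE 0.16), NAALADL2 by 1.43, CSTPP1 by 1.42, SSH2 by 1.4 (SE 0.11, adjusted p = 0.000159), TAS2R14 by 1.4, CLYBL by 1.34, PLCB1 by 1.33, ZHX2 by 1.3 and PEMT by 1.26. Lower values with siCTBP1-AS than with siPSF were -1.53 for CFAP69 (SE 0.19, adjusted p = 0.00372), -0.8 for PAPOLA, a poly(A) polymerase gene, -0.76 for PLEKHH1, -0.75 for BAG2, -0.66 for MYH10, -0.64 for PSPC1 and LINC00472, -0.63 for GOLM2, -0.62 for GAB2 and -0.58 for ACOT9. Of 11 paraspeckle genes SFPQ was higher and PSPC1 lower, also over the list alone. Limma called 0 of 27 interferon genes, with 0 at an unadjusted p under 0.05 and a median of 0.39 (camera adjusted p = 0.234). In VCaP, the set that held both knockdowns, the direct difference had the opposite sign, with interferon medians of -0.65 in vehicle and -1.06 in R1881 and 0 of 27 genes above 0. It called 0 of 17 immediate early genes, with 2 at an unadjusted p under 0.05 and a median of 0.2, and 0 of 27 DNA replication genes, with 0 at an unadjusted p under 0.05 and a median of -0.23. Camera called these lists (adjusted p = 0.0283 and 0.0478), with an adjusted p of 0.977 for each with an estimated correlation. A fit of the 6 VCaP arrays alone, without product terms, called 430 genes, 233 higher and 197 lower, of which 58 were among the 91. There 15 of 28 interferon genes were lower with siCTBP1-AS than with siPSF, and 24 over the list alone (median -0.81, camera adjusted p = 4.14e-25, and adjusted p = 0.672 with an estimated correlation). In sterol synthesis 6 of 18 genes were lower, and 13 over the list alone (median -0.44, camera adjusted p = 6e-10, and adjusted p = 0.672 with an estimated correlation). Camera also called DNA replication, mitosis and fatty acid genes lower (adjusted p = 1.96e-05, 0.00157 and 0.000359) and immediate early and neuroendocrine genes higher (adjusted p = 7.68e-07 and 0.0191), with adjusted p of 0.962, 0.962, 0.675, 0.672 and 0.942 with an estimated correlation. PSPC1, GOLM2, MYH10, ACOT9 and GAB2 did not pass there (adjusted p = 0.083, 0.0785, 0.0583, 0.0688 and 0.16). That fit took its spread from the vehicle and R1881 arrays of 1 set and was chosen after seeing the data. In LNCaP, where the knockdowns had different control arrays, the siCTBP1-AS and siPSF effects correlated at 0.06 across genes, which are not independent replicates. The same knockdown correlated at 0.29 between sets 1 and 2 for siCTBP1-AS and at 0.18 between set 3 and VCaP for siPSF. Across lines, siPSF in VCaP correlated with siCTBP1-AS at 0.35 in set 1 and 0.19 in set 2. For siCTBP1-AS in VCaP and siPSF in set 3 it was 0.2, so the 0.06 does not show unrelated effects. Leaving out a set gave 32 genes without set 1, 46 without set 2, 65 without set 3 and 3 without VCaP.

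The study's stated interest was androgen-dependent change after each knockdown, tested as the difference between the R1881 responses. With siCTBP1-AS in LNCaP limma called 0 genes, with 277 (2.01%) at an unadjusted p under 0.05, fewer than that threshold gives by chance. The smallest p-values belonged to PIK3R1 at 1.13 (SE 0.19), PRKCA at -1.34 (SE 0.25), GRB10 at 0.88, EPS8 at 0.86 and GADD45G at -1.62. Among androgen-induced genes the values were -2.2 for STEAP4, -1.44 for HPGD and -1.19 for NDRG1, and KLK3 had 0.22 and CTBP1 0.53. List medians were -0.36 for androgen-induced genes, -0.46 for hypoxia, -0.33 for cholesterol, -0.28 for fatty acid, 0.5 for interferon, -0.14 for immediate early and 0.44 for androgen-repressed genes. Limma called 0 genes in each of them, over all genes and over the list alone, with 3, 6, 2, 1, 1, 1 and 1 at an unadjusted p under 0.05. Camera called these 7 lists (adjusted p = 2.39e-08, 1.75e-14, 2.87e-06, 0.000456, 0.000405, 0.00403 and 0.0486), and adjusted p with an estimated correlation was 0.384 for the first 4 lists, then 0.569, 0.478 and 0.517. Within sets 1 and 2 the medians of these lists were -0.12 and -0.75, -0.81 and -0.27, -0.11 and -0.56, -0.23 and -0.43, 1.41 and 0.08, -0.18 and 0.01, and 0.1 and 0.71, so the interferon and hypoxia values rested mainly on set 1 and the androgen and cholesterol values on set 2. On only these sets camera did not call the immediate early and androgen-repressed lists (adjusted p = 0.164 and 0.126), and the interferon median was 0.76. There it called DNA replication (median -0.3, adjusted p = 6.41e-06) and mitosis genes down (median -0.12, adjusted p = 0.00752) and the unfolded protein response up (median 0.34, adjusted p = 0.00438), with adjusted p of 0.494, 0.593 and 0.593 with an estimated correlation. In the fit of 12 arrays these medians were 0.09, 0.17 and 0.1. In each of these 3 lists limma called 0 genes on only sets 1 and 2, with 1, 1 and 0 at an unadjusted p under 0.05.

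With siPSF limma called 0 genes for the changed androgen response, with 268 (1.94%) at an unadjusted p under 0.05, fewer than that threshold gives by chance. The smallest p-values belonged to SEC1P at -0.92 (SE 0.21), HES1, a target of Notch signalling, at -0.83 (SE 0.19), GIPC3 at -0.62, TRIB1 at 0.82 and HSP90AA6P at 0.64. In that fit the siControl response of LNCaP was shared by its 3 sets, so a list value need not lie between those of set 3 and VCaP. Fitted list medians were -0.18 for androgen-induced genes, 0.22 for androgen-repressed genes, -0.2 for cholesterol, -0.28 for fatty acid, 0.34 for the unfolded protein response, -0.18 for hypoxia and -0.15 for leukocyte markers. Limma called 0 genes in each, with 0 at an unadjusted p under 0.05 except CD79A among the leukocyte markers, which at -0.51 passed over the list alone. Camera called these lists (adjusted p = 0.0307, 0.0393, 0.0393, 0.0307, 0.00196, 0.0198 and 0.0288), with an adjusted p of 0.73 for each with an estimated correlation. Within set 3 and VCaP the medians were -0.1 and 0.09 for androgen-induced genes, 0.16 and 0.71 for androgen-repressed genes, -0.19 and -0.14 for cholesterol, -0.09 and -0.2 for fatty acid, -0.01 and 0.1 for the unfolded protein response, -0.1 and 0.07 for hypoxia and -0.07 and -0.22 for leukocyte markers. On only these sets limma again called 0 genes, with 303 at an unadjusted p under 0.05, and camera did not call the androgen-induced, cholesterol, unfolded protein response, hypoxia and leukocyte lists (adjusted p = 0.422, 0.113, 0.422, 0.577 and 0.0619). It still called the androgen-repressed list (median 0.49, adjusted p = 4.05e-05) and the fatty acid list (median -0.16, adjusted p = 0.0429), and also the DNA replication list (median 0.36, adjusted p = 1.76e-06), with an adjusted p of 0.956 for each with an estimated correlation. With siCTBP1-AS over both lines limma again called 0 genes, with 482 (3.49%) at an unadjusted p under 0.05, also fewer than by chance. The smallest p-values belonged to PKIB at 0.86, PIK3R1 at 0.93, C9orf43 at 0.59, RNPC3 at 0.85 and TRIB1 at 0.73. There the medians were -0.3 for androgen-induced genes and for hypoxia, -0.26 for cholesterol, -0.25 for fatty acid and -0.15 for fibroblast markers. Limma called 0 genes in each list, with 3, 1, 0, 1 and 0 at an unadjusted p under 0.05. Camera called all 5 (adjusted p = 4.72e-06, 3.01e-06, 0.000831, 0.0019 and 0.0291), and adjusted p with an estimated correlation was 0.388 for androgen-induced, hypoxia and fibroblast genes and 0.464 for the other two. In VCaP the medians were 0.05 for androgen-induced genes, 0.08 for hypoxia, -0.11 for cholesterol, -0.03 for fatty acid and -0.15 for fibroblast markers. On only the sets that held siCTBP1-AS camera did not call the fibroblast list (adjusted p = 0.172). Fry called 0 lists in any of these 3 comparisons.

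To keep the choice of genes apart from the arrays they were tested on, R1881-responsive genes were also chosen on siControl arrays of the other sets. For genes higher with R1881 in set 3 and VCaP, the median response in set 2 was 1.72 with siControl and 0.81 with siCTBP1-AS, and 111 genes (95.69%) responded less. In set 1 the medians were 1.08 and 1, and 67 genes (57.76%) responded less. Of 132 genes higher in sets 1 and 2, the median response in set 3 was 1.65 with siControl and 1.47 with siPSF, with 99 (75%) smaller. In VCaP it was 1 and 0.9, with 74 smaller. Genes lower with R1881 in the other sets numbered 115 for siCTBP1-AS, with medians of -0.21 and -0.41 in set 1 and -0.34 and -0.12 in set 2. Among those 115 were DNA replication genes such as MCM2, MCM5 and PCNA, whose list was not lower with R1881 in sets 1 and 2. For siPSF they numbered 64, with medians of -1.32 and -1.13 in set 3 and -0.7 and -0.45 in VCaP. Camera called the higher genes down for siCTBP1-AS (adjusted p = 7.4e-16) and for siPSF (adjusted p = 3.93e-07), with adjusted p of 0.312 and 0.184 with an estimated correlation, and fry called neither (adjusted p = 0.725 and 0.394). The lower genes were called up for siPSF by camera (adjusted p = 3.84e-07) and fry (adjusted p = 0.0304), with an adjusted p of 0.051 with an estimated correlation, and not for siCTBP1-AS (camera adjusted p = 0.944). The mean of the set medians of the difference was -0.41 (SD 0.57, 2 sets) for the higher genes with siCTBP1-AS and -0.14 (SD 0.16, 2 sets) with siPSF.

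**Figure D4:**
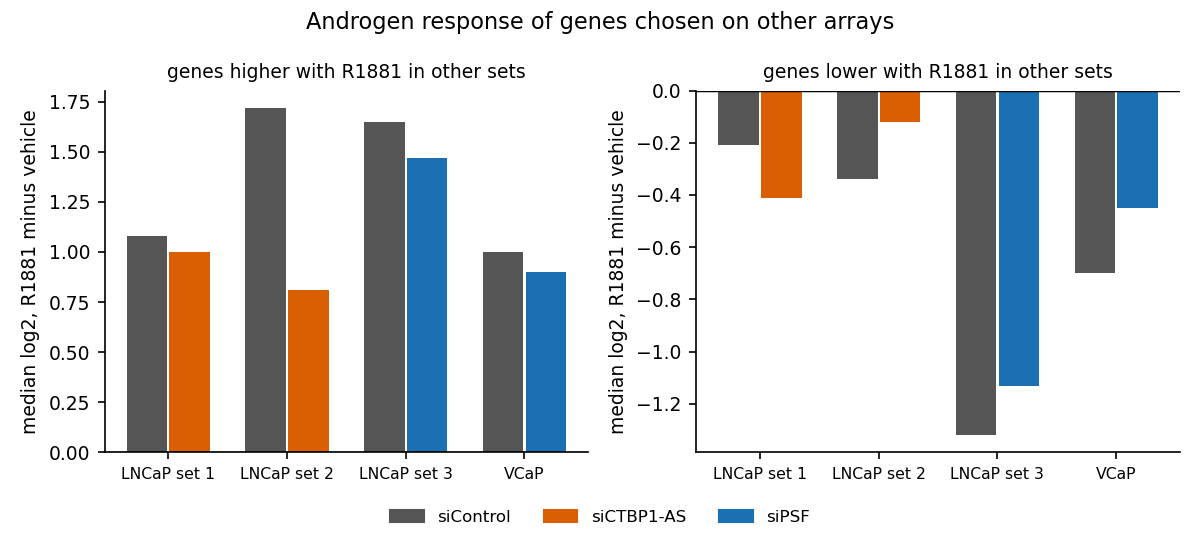
Median log2 response, R1881 minus vehicle, of genes chosen on the siControl arrays of other sets, with siControl and with the knockdown, for genes higher and genes lower with R1881. The largest gap was in LNCaP set 2, where the higher genes had medians of 1.72 with siControl and 0.81 with siCTBP1-AS.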

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

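The test of whether 1 set alone carried the interferon pattern and the test of change by length class were chosen after their results were seen, and the other length tests after the siPSF calls were seen but before their own results.

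Interferon response genes were higher with siCTBP1-AS in LNCaP. That 1 set alone carried the pattern was argued against by medians of 2.91 and 2.22. With siPSF in set 3 the median was 0.01, so the siPSF arrays of LNCaP did not show the pattern. That value rests on 1 siRNA in 1 set with 1 array per treatment. SFPQ also fell less there (11.15 to 10.47 in vehicle) than in VCaP (11.02 to 9.7), so a response of LNCaP to any targeting siRNA is not excluded. In VCaP, where siCTBP1-AS gave 1.14 and siPSF 2.26 against the same siControl arrays, such a response stays open. RNA from leukocytes has no source in the design described, since the samples were transfected cell lines. The marker values alone do not decide it. The 11 leukocyte markers had medians of 0.05 and 0.02 in sets 1 and 2. They were dim, with median signals of 5.96 and 4.5 against 7.26 and 6.46 for all genes. LYZ stood at 2.05 and CD68 at 1.64 in set 1, while the highest of the 11 in set 2 was 0.38. The siRNA molecules and the loss of CTBP1-AS cannot be told apart, because each siCTBP1-AS array carries both, and the median of 1.14 in VCaP does not separate them. A response to the particular siCTBP1-AS duplexes is therefore 1 candidate explanation and a role of CTBP1-AS in interferon signalling another.

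The genes lower with siPSF were long, with a median of 218 kb. Genes over 200 kb had a median change below that of genes under 20 kb by -0.161 in set 3 and -0.16 in VCaP, as a dependence on length predicts, but the rank correlations with length were -0.122 and -0.058, the latter from -0.156 in vehicle and 0.051 in R1881, which leaves length itself open. A length trend of these arrays whatever the siRNA also stays open, since siCTBP1-AS gave -0.107, -0.043 and -0.124, with smaller class differences of -0.044, -0.045 and -0.064, and the R1881 response with siControl, where no knockdown is involved, gave -0.077, -0.177, -0.029 and -0.131 in sets 1, 2, 3 and VCaP, with class differences of -0.078, -0.212, -0.026 and -0.161, small in set 3, which held siPSF, and as large as those of siPSF in set 2 and VCaP. Expression level was argued against by 10000 expression-matched draws, 100% of which had a lower median length. Shared VCaP controls were argued against by the -0.122 in set 3. The same genes had medians of -0.12 and -0.11 with siCTBP1-AS in sets 1 and 2, against -0.63 and -0.71 with siPSF in set 3 and VCaP. They were called as lower on those same siPSF arrays, which enlarges the siPSF values. The siCTBP1-AS medians were also negative, so a smaller fall of these genes with any siRNA stays open. Loss of PSF may lower the expression of some long genes. These arrays do not separate that hypothesis from a length trend of the arrays or from such a fall.

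Genes induced by R1881 in other sets responded less with siCTBP1-AS in set 2, by a median of -0.81, and with siPSF in set 3, by -0.25, against 0 in set 1 and -0.02 in VCaP. Selection on the same control arrays was avoided by taking the genes from other sets, but with the largest of the 4 medians at 0 the sets differ among themselves, and chance in the siControl pair of a set cannot be told apart from an effect of the knockdown. A smaller spread of all genes also stays open, because genes lowered by R1881 elsewhere moved by 0.15 in set 2, towards a smaller response. These genes included DNA replication genes such as MCM2, MCM5 and PCNA, whose list was lower with R1881 in set 3 and VCaP and not in sets 1 and 2. With siControl the chosen genes had medians of only -0.21 in set 1 and -0.34 in set 2, so they say little about genes lowered there. Level differences place the set 2 pattern in the hormone arrays, with -0.03 in vehicle and -0.83 in R1881. The dose of 1 nM in set 2 against 10 nM in set 1, and the different mark on the siRNA, may each matter and were not separated by the design.

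The androgen response differed between VCaP and LNCaP for 491 genes by limma's test of the difference, 226 with a higher value in VCaP, such as MME at 1.91 and CST2 at 3.04, and 265 with a lower one, such as WNT2 at -4.07. In that test 11 of 27 DNA replication genes were lower in VCaP and 24 over the list alone, with a median of -1.08 (camera adjusted p = 8.72e-17, and adjusted p = 0.525 with an estimated correlation), although LNCaP set 3, at -1.05, lay near the -1.61 of VCaP and away from the 0.11 and 0.31 of sets 1 and 2. The siCTBP1-AS effect differed between the lines for 19 genes, among them IFIH1 at -2.45 and MX1 at 2.58, while the interferon list had a median difference of -1.14. The siPSF effect differed for 22 genes, among them MX1, higher in VCaP by 3.94. In all 3 of these tests VCaP was 1 set with its own serum, and its dose of 1 nM was shared in LNCaP by set 2 alone, so the line was not separated from set, serum and dose. For siPSF the LNCaP side was set 3 alone, so its p-values do not measure how the effect varies between sets of a line. Transcript clusters that were not used for a named gene also passed, 5 of 9620 in the androgen response, 25 of 9610 with siCTBP1-AS in LNCaP and 29 of 9503 with siPSF.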

How the results depend on the processing

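No gene named by its rank, or in every comparison, reversed its direction under any alternative where it passed in either setting. Of the genes named from lists, OAS1 and CXCL10 had values of 0.88 and 0.92 for siCTBP1-AS against siPSF, which did not pass, and were lower by 0.8 and 1.55 in VCaP alone. Over the 8 tested comparisons no count of changed androgen responses left 0, and unadjusted counts there ranged from 5 to 869 for siCTBP1-AS in LNCaP, 3 to 786 over both lines and 1 to 455 for siPSF. Where a count moved, the cause was not tested, except that leaving arrays out leaves fewer samples. Leaving out an array or set left arms with 1 sample, which is assumed to vary like the other groups. Background correction was not run as an alternative because the deposited values already hold it. For siCTBP1-AS against siPSF VCaP alone holds both knockdowns, so the fit on that set was made without product terms. That fit and the list tests on only the sets that hold a knockdown were chosen after seeing the data. Signal over background was not given per probe, so how far dim genes are limited by background is unknown.

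The androgen response in LNCaP called 35 genes. It called 57 with the lowest 50% left out, 70 after quantile normalization again, 55 after median centring, 108 with trend and robust, 5898 with array weights, 2 in a fit of group means over all 12 LNCaP arrays and 12 with every cluster tested. With the replicate block, the pairing of arrays within sets, it called 734. Leaving out a replicate gave 0 to 20. Calls with siCTBP1-AS in LNCaP went from 128 to 84 with array weights, 1 without the set block and 613 with a random block, and 145 to 1684 without a replicate. Over both lines 78 became 46 with no filter, 188 with the lowest 50% left out, 47 with array weights, 0 without the set block (limma, 462 at an unadjusted p under 0.05), 365 with a random block, 49 in only the sets that hold the knockdown, 23 with every cluster and 2 to 128 without a set. For siPSF 200 became 330 with array weights, 2 without the block, 54 in only the sets that hold the knockdown and 1 to 146 without a set. For siCTBP1-AS against siPSF 91 became 1 without the block, 430 in the VCaP arrays alone without product terms and 3 to 65 without a set.

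In VCaP, 94.29% of the 35 genes kept their sign as the mean of 3 pairs, and 86.51% of the 734 blocked calls had the same sign, against 97.14%. For the held-out genes higher with R1881, the mean difference with siCTBP1-AS was -0.41 and became -0.22 at a 1.5-fold threshold, -0.7 at 2 and -0.44 with the fixed list, all within the SD of 0.57 between sets. With siPSF it was -0.14 and became -0.08, -0.11 and -0.01, within the SD of 0.16. For the held-out genes lower with R1881, the mean difference with siCTBP1-AS was 0.02 and became 0.06 at a 1.5-fold threshold, 0.87 with a threshold of 2, which left 4 genes, and 0.4 with the fixed list, the last 2 beyond the SD of 0.18 between sets. With siPSF it was 0.24 and became 0.17 at a 1.5-fold threshold, 0.08 at 2, which left 7 genes, and 0.44 with the fixed list, all beyond the SD of 0.05. List calls by camera, 11, 5, 8, 5, 2, 7, 5 and 2 in the order androgen response, siCTBP1-AS in LNCaP and its changed response, siCTBP1-AS over both lines, siPSF and its changed response, changed response to siCTBP1-AS over both lines and siCTBP1-AS against siPSF, and 8 with the replicate block, all became 0 with an estimated correlation. By fry they were 0, 1, 0, 3, 0, 0, 0 and 0. These counts of lists, and those that follow, include the list that is not reported here. On only the sets that hold the knockdown camera called 6, 9, 4, 3, 3 and 4 lists and fry 0, 0, 2, 0, 0 and 0 for the second to the seventh of these comparisons, and 7 for siCTBP1-AS against siPSF in VCaP alone without product terms. The replicate block, an alternative for the androgen response alone, moved its list calls by camera from 11 to 8 and by fry from 0 to 9. List tests without the set block were not run.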

Other observations

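The genes and lists named from the differences between lines were chosen after their values were seen. For siPSF these differences rest on 1 set per line, without a measure of the spread between sets of a line. Proliferation genes differed by set in their response to R1881. DNA replication genes had medians of 0.11 in set 1, 0.31 in set 2, -1.05 in set 3 and -1.61 in VCaP, and mitosis genes of 0.14, 0.1, -0.65 and -0.72, although sets 1 and 3 shared the line and the 10 nM dose. With siPSF, mitosis genes had a median of -0.54 in set 3 and 0.44 in VCaP and DNA replication genes of -0.3 and 0.41. In the test of the difference between lines, limma called 0 mitosis genes for siPSF and 24 were higher in VCaP over the list alone, with a median difference of 1.02 (camera adjusted p = 6.98e-22, and adjusted p = 0.296 with an estimated correlation). The interferon list differed between lines in opposite directions. For siCTBP1-AS the median difference was -1.14, with 3 genes lower in VCaP and 1 higher, and 9 lower and 1 higher over the list alone (camera adjusted p = 3.84e-08, and adjusted p = 0.594 with an estimated correlation). For siPSF it was 1.9, with 4 genes higher in VCaP and 20 over the list alone (camera adjusted p = 4.54e-27, and adjusted p = 0.285 with an estimated correlation). MX1 had 0.48 and 0.3 with siCTBP1-AS in LNCaP sets 1 and 2, against 2.98 in VCaP, where IFIT1 and IFI44L stood at 4.52 and 5.44 with siPSF.

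CTBP1 had R1881 minus vehicle differences with siControl of -0.4 in set 1, -1.19 in set 2, -1.01 in set 3 and -0.38 in VCaP. ERG, which encodes an ETS transcription factor, had signals of 10.38 in vehicle and 12.11 in R1881 in VCaP with siControl, 10.07 and 11.55 with siCTBP1-AS and 9.01 and 10.2 with siPSF, with signals of 3.91 to 5.03 on the LNCaP arrays. The unfolded protein response list had R1881 medians of -0.71 in set 1, 0.37 in set 2, 0.51 in set 3 and 0.44 in VCaP. The R1881 responses correlated across genes, which are not independent replicates, at 0.59, 0.52 and 0.68 between the LNCaP sets and at 0.24, 0.45 and 0.54 with VCaP.

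Other splits of the arrays were counted for each comparison. In the androgen response, 3 of 10 splits of the 6 arrays called at least the real 35 genes, and the highest other split called 100. That split and the next, with 71, put the set 1 pair against the set 2 pair and parted set 3, which points to a structure of the samples by set. The other 3 splits that part all 3 pairs, as the real one does, called 0 genes by limma without the block. With the block, the real split of 4 called 734 and was the only 1, with a highest other of 0, and neither number of splits allows a share under 0.05. The effect of siCTBP1-AS over both lines was called for 78 genes, and 1 of 32 splits, the real one, gave as many, with a highest other of 2. Those splits exchanged the vehicle and R1881 arrays of a set separately, although the contrast rested on sets 1, 2 and VCaP. Since the labels do not state separate cultures, these splits cannot exclude chance. The remaining comparisons with any calls had too few splits for a share under 0.05. For siCTBP1-AS in LNCaP 1 of 8 gave as many as 128 with a highest other of 1, and for siPSF 1 of 8 gave 200 with a highest other of 0. For siCTBP1-AS against siPSF 1 of 12 gave 91 with a highest other of 21. For the changed responses the real count was 0, so every split had to give as many (32 of 32 for siCTBP1-AS over both lines, and 8 of 8 for siCTBP1-AS in LNCaP and for siPSF) and the splits decide nothing. Their highest others were 2, 0 and 12.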
